A study of Mus musculus with 2 samples.

How the data were processed

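The assay was ATAC-seq, in which the transposase Tn5 cuts accessible DNA and the reads mark open chromatin. Hearts of mice aged 4 days were pooled before nuclei were extracted, 7 mice of the genotype Wtapflox/flox and 6 of the genotype Wtap-CKO, a cardiomyocyte-specific knockout of Wtap, per the labels' protocols. Each pool gave 1 library, sequenced as paired ends. The design therefore holds 1 library per genotype and no replicate, so no test between genotypes was run and no p-value is given. Samples were grouped by the genotype in their labels.

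The submitters' processing notes name fastp 0.20.0, BWA 0.7.12, MACS2 2.1.0, HOMER 4.11, ChIPseeker and the build GRCm39, without saying what each was used for. The Tn5 offset of the reads, the removal of duplicates and mitochondrial reads and the threshold of the peak caller are not given in the sources used here. Unremoved duplicates would change the depth and make the counting intervals too narrow. Unremoved mitochondrial reads would change the depth. The authors deposited 1 table of 83549 merged peaks, with 0 overlaps between neighbours, and a mark per library for whether the peak was called there. Counts in the deposited table are whole reads per peak and library, not normalised. The RPM deposited by the authors equals the count plus 1 read, multiplied by 1 constant per library, as worked out from the values. The constants are 0.0171 RPM per read for Wtapflox/flox and 0.01475 for Wtap-CKO; the read totals they imply are not stated in the table. The fold enrichment deposited by the authors is the RPM over that of an even spread of reads for the width of the peak, the same divisor in both libraries. The log2 fold change in the authors' deposited table is the log2 ratio of the RPM values, Wtap-CKO over Wtapflox/flox, with no centring. Each peak also carries an annotated feature, the distance to the nearest transcript start, an Ensembl gene ID and, for some genes, Gene Ontology (GO) terms. Coordinates are GRCm39 and are read as counted from 1.

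Ratios were computed from the counts. Counts were divided by the reads of the library in all peaks, 9835753 for Wtapflox/flox and 9816384 for Wtap-CKO, and scaled to CPM. The log2 ratio of Wtap-CKO over Wtapflox/flox was taken after adding 0.5 to each CPM, which draws the ratio of weak peaks towards 0. Peaks under the 25th percentile of mean CPM (3.92, about 38.5 reads in each library) were left out of counts of higher and lower peaks, and 62662 peaks stayed in. A peak was called higher or lower at a 2-fold difference. Each ratio has an exact conditional binomial (Clopper-Pearson) 95% interval, computed from the counts with no added value. Intervals cover counting error only and not the difference between animals or library preparations. The number of calls that counting error alone would give came from 100 binomial draws with equal rates in both libraries. Intervals of class medians are bootstrap intervals over peaks, which are not replicates.

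Promoter signal was the sum over peaks within 1000 bp of an annotated start, per gene, for 16298 genes. The reference gene table given with the data is of another build and shares 0 of the IDs, and the files do not pair the IDs with symbols. Genes are therefore described by position and by the GO terms in the file. GO terms were given for 13687 of 28944 annotated genes and for 52.7% of peaks; 1784 genes had their terms left out of the table used here. The gene lists fixed before the data were examined were lists of symbols and were replaced by 24 lists built from GO terms, chosen by the name of the term after the annotation had been read and before any ratio of a list had been computed. A list's median log2 ratio was set against 10000 random lists of the same size, drawn from the 11494 genes with GO terms and a promoter peak and matched in 10 bins of mean promoter signal. The percentile among them describes these libraries and is not a test. The gene called Wtap here was taken as the only chromosome 17 gene among the 7 annotated to the RNA methyltransferase complex that Wtap belongs to, since the reference table places Wtap on chromosome 17.

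The rule for items named, written before the data were examined, took Wtap, the 10 genes with the largest rise and the 10 with the largest fall in promoter signal among genes at or above the median signal, the extreme members of each list, and the 5 largest rises and 5 largest falls among peaks at or above the median signal. Mef2a and Mef2c were also in the rule and are not analysed here, since their IDs could not be tied to symbols. The planned comparison of peaks with and without transcription factor motifs needed a genome sequence and was not run. GC content was not checked for the same reason.

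Alternatives set in advance were pseudocounts of 0.1 and 2, centring on the median of all peaks or of promoter peaks, no floor or a floor at the median, size rules of 1.5-fold and 4-fold, a promoter window of 3000 bp, the nearest peak only and all peaks of a gene. Peaks called in 1 library only stood in for a stricter threshold of the peak caller, which is not given. Alternatives chosen after seeing the data were the authors' RPM, which also changes the value added before the ratio, the library totals implied by that RPM with the pseudocount kept, the data without the 20 largest peaks, chromosomes 1 to 19 only, peaks outside promoters only, removal of the trend with signal in 50 bins, and random lists matched on signal together with promoter width or transcript length in 5 bins. The 4 heart muscle lists were joined, all GO terms with 15 to 500 genes were scanned, and genes with several called peaks were counted at 2 scales, also after seeing the data. The steps were tested on data simulated for the promoter signals of 16298 genes. There 25 of 25 genes with a true 4-fold rise were called higher, and 4 of 16098 unchanged genes were called with no floor, 0 of 12024 over it. Of 60 unchanged lists, 2 lay in the lowest or highest 2.5%, and 19 of 20 lists of 40 genes lowered by 0.1 lay below the 2.5th; the simulated genes varied by counting error alone. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.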

Results

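Chromatin accessibility was measured by ATAC-seq in hearts of 4-day-old mice, in 1 pool of 7 Wtapflox/flox mice and 1 pool of 6 Wtap-CKO mice. Wtap is a subunit of the nuclear complex that places N6-methyladenosine (m6A) on RNA, and it was deleted in cardiomyocytes only, so the other cells of the heart kept the gene. The comparison asked how loss of Wtap in cardiomyocytes altered open chromatin in the heart. The Wtapflox/flox library had 9835753 reads in 83549 peaks, with a median of 64 reads per peak, and the Wtap-CKO library had 9816384, with a median of 67. The totals implied by the authors' scaling put 16.8% of reads in peaks for Wtapflox/flox and 14.5% for Wtap-CKO. With 1 library per genotype, no difference has a replicate check, and every statement below compares these 2 libraries.

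The promoter of Wtap was about equally accessible in both libraries. The gene taken to be Wtap (ENSMUSG00000060475, chromosome 17, 13185683 to 13211384, GRCm39) had 1 peak, which overlapped its start (13210546 to 13211906). It held 606 reads in Wtap-CKO and 651 in Wtapflox/flox, a log2 ratio of -0.10 (95% counting interval -0.26 to 0.06), and -0.32 in the authors' deposited table. The labels do not give the deleted part of the gene, and a promoter peak outside it checks nothing, so the genotype of the libraries was not checked by these data.

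Most of the open chromatin was shared by the genotypes, and peaks at promoters differed less often than peaks elsewhere. Of 83549 peaks, 51121 (61.2%) were called in both libraries, 14710 only in Wtap-CKO and 17718 only in Wtapflox/flox. Peaks called in 1 library also held reads in the other. Those called only in Wtap-CKO had a median of 45 reads there and 25 in Wtapflox/flox. Those called only in Wtapflox/flox had 41 there and 29 in Wtap-CKO. Among the 62662 peaks over the signal floor, 2195 (3.50%) were at least 2-fold higher in Wtap-CKO and 909 (1.45%) at least 2-fold lower. Of the higher peaks, 1646 were called only in Wtap-CKO, and of the lower peaks 662 only in Wtapflox/flox. Of the 20444 peaks within 1000 bp of a start over the floor, 282 (1.38%) were higher and 172 (0.84%) lower, against 1913 (4.53%) and 737 (1.75%) of the 42218 others. Promoter peaks also had more signal (median CPM 14.2, against 5.55 for the others, over all peaks), which narrows their ratios. Counting error alone gave at most 11 higher and 8 lower peaks in 100 draws, which leave out any difference between pools or preparations. The balance of higher and lower peaks depended on the scaling: with the authors' RPM, which shifts the median log2 ratio by -0.22, 1265 peaks were higher and 2906 lower, and with the library totals behind the RPM but the same pseudocount 1004 were higher and 2297 lower. Higher peaks made up 70.7% of calls by reads in peaks, 30.3% by RPM, 30.4% by the library totals, 69.5% when centred on all peaks and 78.2% when centred on promoter peaks.

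The largest rise lay on chromosome 4 (148089336 to 148089578), within 1000 bp of an annotated start, with 141 reads in Wtap-CKO against 9 in Wtapflox/flox (log2 ratio 3.39, interval 3.01 to 5.13). Intron 7 of 43 of a cation channel gene on chromosome 14 (123768518 to 123769149) had 120 reads against 18 (log2 ratio 2.45). Intron 4 of 31 of a gene on chromosome 15 (76284034 to 76284509) had 137 against 22 (2.40). The other large rises were an intergenic peak on chromosome 1 (155945906 to 155946263, 116 reads against 19) near a gene with nuclear envelope terms, and a promoter peak on chromosome 10 (39433884 to 39434255, 136 against 24). The largest fall, on chromosome 1 (24651582 to 24652061), overlapped a start site and went from 1508 reads in Wtapflox/flox to 52 in Wtap-CKO (log2 ratio -4.73, interval -5.28 to -4.46). The mapping of reads to this peak was not checked. Exon 6 of 23 of a microtubule motor gene on chromosome 1 (179558942 to 179559396) had 11 reads in Wtap-CKO against 136 (-3.14). Falls also lay on chromosome 9 (123730333 to 123730645, -2.52, intergenic), chromosome 19 (24653792 to 24654306, -2.12) and chromosome 13 (14263258 to 14263740, -2.12).

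The rise on chromosome 4 was part of a run of 7 neighbouring peaks (148063849 to 148093172), singled out after their values were seen. The run was extended from the largest rise to each side for as long as the log2 ratio stayed above 0. Together they held 1924 reads in Wtap-CKO and 1050 in Wtapflox/flox, a log2 ratio of 0.88 (interval 0.77 to 0.99), and 0.78 without the largest rise. The run contains a gene whose GO terms include hormone activity, cGMP biosynthesis and blood pressure regulation. A peak 2045 bp from the start of that gene (148072290 to 148073530) had 527 reads against 193 (log2 ratio 1.43, interval 1.21 to 1.70). The peak over the start itself (148069756 to 148070444) differed less, with 454 reads against 400 (0.18, interval -0.01 to 0.38). A peak at -155 bp from the start of another annotated gene (148085179 to 148086536) had 250 reads against 127 (0.95, interval 0.67 to 1.30). The gene to which the largest rise was annotated had a further peak within 1000 bp of its start, with 171 against 87 (0.94, interval 0.60 to 1.37).

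**Figure D1:**
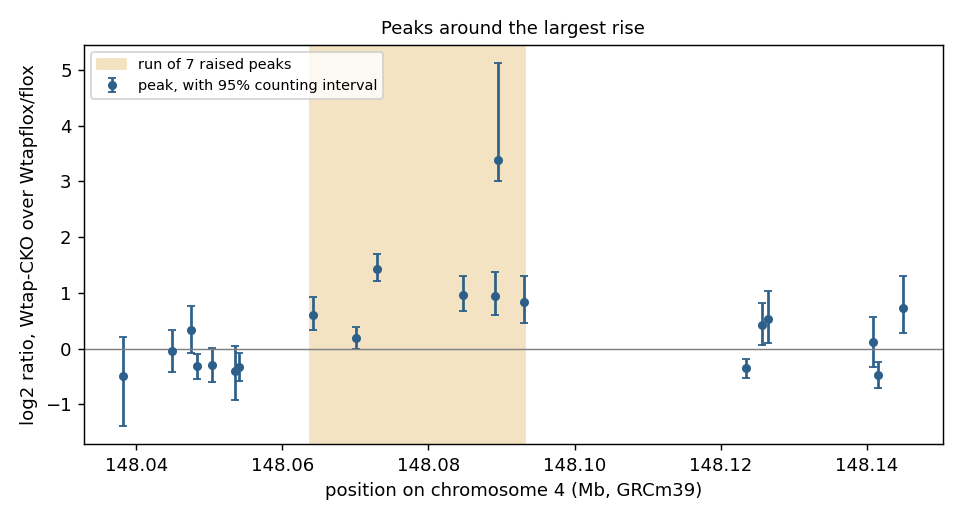
Log2 ratios of peaks (y axis, Wtap-CKO over Wtapflox/flox) by position on chromosome 4 (x axis, Mb, GRCm39), with bars for the 95% counting interval and shading for the run of 7 peaks. Ratios in the run lie between 0.18 and 3.39, and the nearest peak on each side lies at -0.32 and -0.35. The run was extended while ratios stayed above 0, so these signs follow from how it was drawn.

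Promoter peaks were slightly less accessible in Wtap-CKO than peaks elsewhere, relative to the reads in peaks. The 22815 peaks within 1000 bp of a start had a median log2 ratio of -0.06 (bootstrap interval -0.07 to -0.06), and the other 60734 peaks one of 0.05 (0.05 to 0.06). Intergenic peaks had a median of 0.06, introns 0.04, exons 0.08, 3' UTRs 0.08 and peaks downstream of genes 0.11, whereas the 80 peaks in 5' UTRs had -0.06 (-0.12 to 0.03). Promoters also took a smaller share of the reads in peaks in Wtap-CKO (48.7%) than in Wtapflox/flox (50.3%). By the authors' RPM both medians were negative, -0.28 for promoter peaks and -0.16 for the others, so the sign outside promoters depended on scaling. Medians of the 19 autosomes lay between -0.01 and 0.03. Peak reads on the Y chromosome gave a log2 ratio of 0.16 (interval 0.08 to 0.24) and those on X one of -0.04 (-0.05 to -0.03); the sexes of the pooled mice are not given in the labels.

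**Figure D2:**
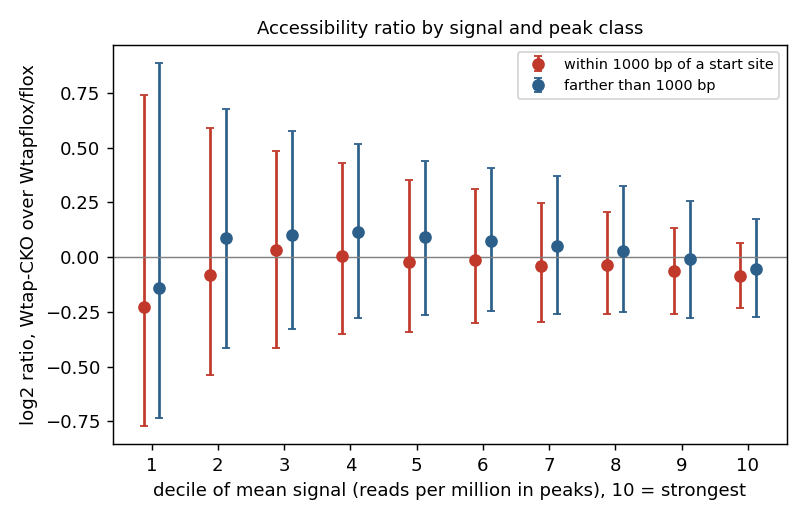
Median log2 ratio (y axis, Wtap-CKO over Wtapflox/flox) in deciles of mean signal (x axis, 10 the strongest) for peaks within 1000 bp of a start site and farther away; bars span the 25th to 75th percentile of peaks. Promoter peaks have the lower median in every decile, and in decile 10 the medians are -0.09 and -0.06.

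Promoter signal of single genes differed little between the libraries. Of 16298 genes with a promoter peak, 12223 were over the floor, and 92.7% of these lay within 0.5 of a log2 ratio of 0. At the 2-fold rule 24 genes were higher and 22 lower in Wtap-CKO, against a largest count of 0 in either direction over the floor from counting error alone. The authors' RPM gave 6 higher and 101 lower. Of the 10 named falls, 6 were of genes with GO terms. A promoter on chromosome 15 (76905307 to 76907130, ENSMUSG00000018893), of a gene annotated to oxygen transport, heme binding and heart development, had 282 reads in Wtap-CKO against 652 (log2 ratio -1.19, interval -1.41 to -1.003). An acyltransferase gene of the endoplasmic reticulum on chromosome 9 (121620314 to 121621660) had 290 against 636 (-1.12), and an amino acid transporter gene on the same chromosome (107543973 to 107547906) had 184 against 384 (-1.04). A desmosome and intercalated disc gene on chromosome 13 (38335013 to 38335566) had 160 against 319 (-0.97), just short of 2-fold; desmosomes join cardiomyocytes mechanically. The 2 others with terms, on chromosomes 7 and 6, had ratios of -0.97 and -0.92. Of the 10 named rises, 1 had GO terms: a subunit of acetylcholine-gated ion channels on chromosome 14 (66378065 to 66379194, ENSMUSG00000022041), with 379 reads against 135 (1.46, interval 1.20 to 1.79). The 9 rises without terms ran from 0.79 to 1.68, the largest on chromosome 7 (89678854 to 89680264, 379 against 115). Among them were neighbouring promoters on chromosome 17 with very many reads, 78151 against 44753 (40153872 to 40158208, 0.81) and 24049 against 12980 (40158375 to 40159694, 0.89). The former held the largest count of any peak in both libraries, and the mapping of reads there was not checked. The 4 falls without terms were the chromosome 1 peak at -4.73 and promoters on chromosomes 19 (-1.30), 17 (-1.19) and 4 (-0.93).

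Genes of the contractile apparatus had lower promoter accessibility in Wtap-CKO than matched random genes, by a small amount. The median log2 ratio of 150 sarcomere promoters was -0.15, against -0.08 for random lists of the same signal, at the 0.15th percentile. Of these 150, 103 lay below the median of all genes with GO terms (-0.06). The counting interval lay below 0 for 60 (40%) and above 0 for 13 (8.67%) of the 150, against 24.3% and 11.7% of all genes with GO terms. Those genes were not matched on signal, and the width of such intervals depends on the read counts. Promoters of 33 sarcoplasmic reticulum genes, which store and release the calcium that drives contraction, had a median of -0.18 (2.18th percentile), which was not below the 2.5th in 5 of 11 alternatives, such as the nearest peak only (9.06th). Heart contraction and rhythm genes (45) had -0.16 (2.57th percentile) and intercalated disc genes (25) -0.16 (8.44th). No member of these lists over the floor passed 2-fold. The lowest members were a cardiac myofibril myosin gene on chromosome 2 (155452882 to 155453311, 133 reads against 237, -0.81, interval -1.15 to -0.52), a ryanodine-sensitive calcium release channel gene on chromosome 2 (113047290 to 113047810, 79 against 127, -0.65) and the desmosome gene on chromosome 13, lowest in both remaining lists. The highest were a Z disc gene on chromosome 14 (0.66, 333 against 210), a mannosyltransferase gene on chromosome 2 (0.49), a collagen gene on chromosome 3 (0.41) and a titin-binding gene on chromosome 1 (0.13). Taken outside promoters, where random lists lay above 0, sarcomere genes had a median of 0.02 against 0.05 for random lists (19.2th percentile), and heart contraction genes one of -0.10 (0.34th percentile). Of the 24 lists, 2 fell below the 2.5th percentile and 0 were in the top 2.5%, with 0.6 given by chance at each end. These 2 lists share 9 genes, so they are not separate results, and with matching on promoter width 1 list lay below and 1, cytosolic ribosome, in the top 2.5%.

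**Figure D3:**
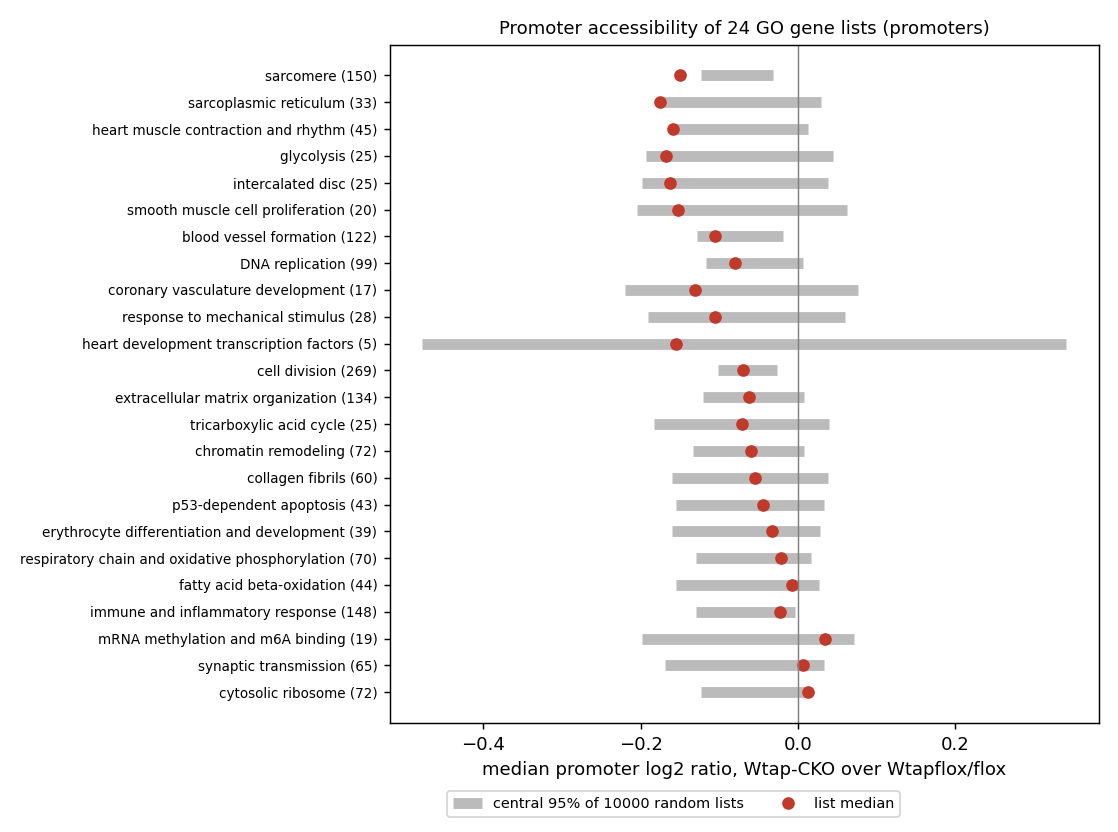
Median promoter log2 ratio of 24 GO gene lists (points, x axis, Wtap-CKO over Wtapflox/flox; number of promoters in brackets) and the central 95% of 10000 random lists matched on signal (grey bars). The sarcomere (-0.15) and sarcoplasmic reticulum (-0.18) lists lie below their bars, and the cytosolic ribosome list (0.01) is the highest by percentile.

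By promoter signal, lists of metabolic genes lay on both sides of the middle of the random lists, and all within their range. The promoters of 25 glycolysis genes had a median of -0.17 (5.78th percentile), with an aldolase gene on chromosome 11 lowest (-0.73) and a hexokinase gene on chromosome 10 highest (0.41). Outside promoters, glycolysis genes (19) lay below the range, with a median of -0.20 against 0.07 for random lists (0.565th percentile). Fatty acid oxidation genes (44) had -0.01 (88.5th percentile), from a carnitine palmitoyltransferase gene at -0.37 to an acetyl-CoA acetyltransferase gene at 0.46. Respiratory chain genes (70) had -0.02 (83.0th), from -0.62 to 0.68 for a mitochondrial transcription elongation gene on chromosome 11. Tricarboxylic acid cycle genes (25) had -0.07 (50.4th), from a pyruvate dehydrogenase gene on X at -0.43 to an aconitase gene on chromosome 15 at 0.45. None of these lists had a member over the floor at 2-fold, and the extremes named for lists are of members over the floor.

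The lists chosen for mRNA methylation, chromatin and cell growth lay within the range of random lists. The 19 promoters of the mRNA methylation and m6A binding list had a median of 0.03 (92.1th percentile), from -0.26 to 0.33 for a gene with methyltransferase terms on chromosome 3. Cytosolic ribosome genes (72) had 0.01 (96.9th), chromatin remodeling genes (72) -0.06 (53.6th), cell division genes (269) -0.07 (34.3th), DNA replication genes (99) -0.08 (20.5th) and p53-dependent apoptosis genes (43) -0.04 (63.9th). Extremes were ribosomal protein genes at -0.52 and 0.51, chromatin remodeling genes at -0.53 and 0.58, cell division genes at -0.84 and 0.78, DNA replication genes at -0.88 and 0.80, and apoptosis genes at -0.61 and 0.50. The list of heart development transcription factors had only 5 promoters (median -0.15, 33.5th percentile), and those over the floor ran from -0.15 to 0.06. Genes of the response to mechanical stimulus (28) had -0.11 (26.9th, from -0.37 to 0.43).

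By promoter signal, lists tied to other cells of the heart also lay within the range of random lists. Blood vessel formation genes (122) had a median of -0.10 (13.6th percentile), smooth muscle proliferation genes (20) -0.15 (11.1th) and coronary vasculature genes (17) -0.13 (22.5th). Collagen fibril genes (60) had -0.05 (55.4th), extracellular matrix genes (134) -0.06 (40.5th), erythrocyte development genes (39) -0.03 (77.0th), immune genes (148) -0.02 (92.1th) and synaptic transmission genes (65) 0.01 (92.99th). Over the floor, the immune list held 1 gene above 2-fold, an inflammatory response peptidase gene on chromosome 8 (260 reads against 116, 1.13), and the synaptic list 1, the acetylcholine-gated channel gene. Other extremes ran from -0.87 for an extracellular matrix gene on chromosome 15 to 0.56 for a blood vessel formation gene on chromosome 9. With all peaks of a gene in place of promoters, the immune list (0.07, 99.88th percentile) and the extracellular matrix list (0.04, 99.48th) rose above the range. GO lists are broader than marker sets, and many of their genes are active in more than 1 cell type.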

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

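The comparison rests on 1 library per genotype, so no replicate could be left out and no paired analysis was possible. The difference between promoter and other peaks kept its sign, from -0.12 with the authors' library totals to -0.093 with a floor at the median. Centring cannot move this difference, and neither can leaving out the floor, which the class medians did not use. The Wtap promoter ratio stayed below 0 in all 8 alternatives, from -0.32 to -0.04. These reuse the same reads, so the kept sign is no separate evidence. The counting interval of the main setting (-0.26 to 0.06) spans 0. Rescaling and centring shift a list and its random lists almost alike, so they are not counted for percentiles. In the other 11 alternatives, sarcomere promoters stayed below the 2.5th percentile in 9; the exceptions were all peaks of a gene and peaks outside promoters. The 4 heart muscle lists together (214 promoters, median -0.14, 0.06th percentile) did so in 9 and sarcoplasmic reticulum in 6 (not with the nearest peak, 9.06th, a 3000 bp window, 5.11th, outside promoters, 3.01th, or matching on transcript length, 4.27th, or width, 2.65th), and heart contraction lay below it in 6, but at -0.071 (46.9th) with a 3000 bp window and -0.061 (21.8th) with all peaks of a gene. The cause of the changes below was not tested unless named.

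With a pseudocount of 2, 905 peaks were higher and 361 lower, 14 genes were higher, and the class medians were -0.055 and 0.043 with a difference of -0.098. Without a floor the counts were 5295 and 2613 peaks and 256 and 201 genes, since weak peaks enter. A floor at the median gave 802 and 417 peaks, 5 and 6 genes, a non-promoter median of 0.029 and a difference of -0.093. The 1.5-fold rule gave 7678 and 5190 peaks and 199 and 308 genes, and the 4-fold rule 66 and 15 peaks and 0 and 1 genes, by construction.

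Centred on promoter peaks, the promoter median was 0 by construction, the non-promoter median 0.11, sarcomere -0.090 and the 4 lists together -0.082. A 3000 bp window gave 70 higher and 33 lower genes. The nearest peak only gave 34 higher and 35 lower genes. It put 3 lists below the 2.5th percentile (sarcomere, heart contraction and intercalated disc) and 1 list in the top 2.5%, cytosolic ribosome. All peaks of a gene gave 183 higher and 60 lower genes, 1 list below the 2.5th percentile and 2 in the top 2.5% (immune and extracellular matrix), with sarcomere at -0.073 and the 4 lists together at -0.062.

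Alternatives chosen after seeing the data follow. The authors' RPM gave 1265 higher and 2906 lower peaks, 6 and 101 genes, class medians of -0.28 and -0.16 (the latter reversed), Wtap -0.32, sarcomere -0.37, sarcoplasmic reticulum -0.39 and the 4 lists together -0.36. It also changes the value added before the ratio. The library totals behind it with the pseudocount kept gave 1004 and 2297 peaks, 6 and 81 genes, class medians of -0.27 and -0.15 (the latter reversed) with a difference of -0.12, Wtap -0.31, sarcomere -0.36, sarcoplasmic reticulum -0.39 and the 4 lists together -0.35, so the scale by itself gave most of the shift. Outside promoters, sarcomere (0.023) and the 4 lists together (0.0071) changed sign but stayed below their random medians (0.050 and 0.053), and sarcoplasmic reticulum was -0.067. Without the 20 largest peaks the class medians were -0.050 and 0.062. With the signal trend removed, sarcomere was -0.081 and the 4 lists together -0.074. Matching on promoter width left 1 list below the 2.5th percentile and 1 in the top 2.5% (cytosolic ribosome). A stricter threshold of the peak caller could not be applied, since none is given. Peaks called in 1 library only, which are not a stricter set, gave 1646 higher and 662 lower peaks. The motif comparison with its alternatives, Mef2a and Mef2c, and the lists of symbols were not run. Depth limits single peaks: near the floor of about 38.5 reads per library, counting error alone spreads ratios widely.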

Other observations

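The scans and the tests of explanations in this part were chosen after the results they bear on had been seen. Promoters of 1317 GO terms were ranked against matched random lists. Of these terms 12 lay below the 0.1th percentile of matched random lists and 10 in the top 0.1%, with 1.32 given by chance at each end, although terms share genes. Lower in Wtap-CKO were the promoters of delayed rectifier potassium channels (15 genes, median log2 ratio -0.47), which repolarise excitable cells, potassium ion transport (72, -0.21), actin binding (255, -0.14), actomyosin structure organization (21, -0.28), cell-cell junctions (94, -0.18) and the basolateral plasma membrane (117, -0.20). Neuron differentiation (60, -0.24) and neurotransmitter transport (24, -0.36) were lower too, so the direction was not limited to heart muscle terms.

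The terms at the upper end were of several kinds. Complex I assembly (43 genes) had a median of 0.12, with 7 below the background median; complex I oxidises NADH in the respiratory chain. The catalytic step 2 spliceosome (67) had 0.07, rRNA processing (114) 0.05, translation (221) 0.03, mitochondrial inner membrane (298) -0.00 and RNA methylation (17) 0.20. Peroxisomal membrane (41, 0.07), cellular response to interferon-beta (18, 0.22) and protein localization to cilium (31, 0.10) were also high, short of the top 0.1%. The lists of respiratory chain, tricarboxylic acid cycle, fatty acid oxidation, cytosolic ribosome and mRNA methylation genes lay within the range of random lists in the main setting, the cytosolic ribosome list near its upper end (96.9th percentile) and in the top 2.5% in 2 of 11 alternatives. Structural constituent of ribosome (129, 0.03) was among the terms in the top 0.1%. Outside promoters, 977 terms gave 2 below the 0.1th and 2 in the top 0.1%, with 0.977 given by chance at each end.

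The first pattern weighed is the lower promoter signal of sarcomere genes. The random lists of the main setting were already matched on signal, with sarcomere genes at the 0.15th percentile. Removing the trend of the ratio with signal (0.05th) was therefore hardly a separate check. Among lists matched on signal and promoter width, sarcomere genes lay at the 0.1th percentile. The matching argues against either signal or width as the whole cause. A lower share of cardiomyocyte nuclei in the Wtap-CKO pool may also lower these promoters. The 7 lists for other cell types lay between the 11.1th and 92.99th percentile, 4 of them at or above the 50th, within the random range. With all peaks of a gene the immune list left that range (0.066, 99.88th percentile), and none fell below it. The lists decide neither way, and the share of cells cannot be told apart from a change within cardiomyocytes. GC content was not tested, and an effect of losing Wtap stays open and untested.

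The second is the raised run on chromosome 4. The 65 other peaks within 500 kb had a median log2 ratio of 0.078 (bootstrap interval -0.10 to 0.28), against 0.88 for the run, which argues against a copy number or mapping change of the wider region. Of 6805 overlapping windows of 7 neighbouring peaks with at least as many reads, 3 were as high as the run. The run is itself among them and was chosen for its high ratios, so this rank restates that choice. A response of heart cells to the loss of Wtap is a hypothesis that 1 library per genotype cannot separate from a difference between the pools.

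The third is the excess of higher over lower peaks. With the authors' library totals in place of reads in peaks, and nothing else changed, it turned to 2297 lower against 1004 higher, so its direction depends on the scale. Among peaks outside promoters called in both libraries, the median log2 ratio was 0.16 in the weakest 25% by fold enrichment and -0.06 in the strongest, a difference of 0.22 (bootstrap interval 0.20 to 0.23). More background reads in the Wtap-CKO library would raise weak peaks in this way. Among all peaks outside promoters the difference was 0.18 (0.15 to 0.21) by fold enrichment, but by mean signal the weakest and the strongest 25% had nearly the same median (0.0025 and 0.0028). In the weakest 25%, 82.9% of peaks by fold enrichment and 95.6% by mean signal were called in 1 library only, so both comparisons depend on how peaks were called. In deciles of mean signal, the median outside promoters was -0.14 in decile 1, 0.12 in decile 4 and -0.06 in decile 10. It fell at each step from decile 4 on. The nearly equal medians of the weakest and strongest 25% by mean signal thus hide a rise and a fall. The totals implied by the authors' scaling put 14.5% of reads in peaks for Wtap-CKO and 16.8% for Wtapflox/flox. The dependence on scale comes from this same difference, so scale and background are not separate matters. Background reads stay open as a cause, as does a genotype effect that opens weak sites. Both stay open for the lower median of promoter peaks too, since these peaks had more signal.

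Called peaks gathered at some genes, in a direction that depended on the scale. By reads in peaks, 40 genes had 3 or more higher peaks, against a mean of 17.04 and a largest count of 30 in 1000 shuffles among peaks of like signal and class. Lower peaks gave 5 such genes, against a mean of 1.56 and a largest count of 7. By the authors' library totals, higher peaks gave 7 such genes (mean 2.19, largest 7) and lower peaks 42 (mean 18.3, largest 32). A gene on chromosome 17 (peaks from 28626358 to 28737398) had 4 of its 6 peaks higher by reads in peaks, with 1506 reads in Wtap-CKO against 772.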
